A study of Mus musculus with 6 samples.

How the data were processed

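RNA from 6 whole primary mammary tumours of female BALB/c mice was measured on Affymetrix mouse expression arrays, 1 array per tumour. Per the labels' protocols, 100000 cells of 4T1.2, a mouse mammary carcinoma line, were placed in the 4th inguinal mammary fat pad of mice 6 to 8 weeks old. Tumours were excised at about 0.3 g, and total RNA was purified on columns and labelled with biotin by a kit that primes from the 3' end of transcripts. In 3 tumours the cells carried the empty retroviral vector pBabepuro (control tumours 1 to 3), and in 3 they carried the vector with mouse Bmp4 (Bmp4 tumours 1 to 3). Groups and tumour numbers were taken from the labels. The labels do not state that each tumour came from a separate mouse, so the p-values measure the spread between these tumours.

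The deposited values are log2 expression per probe set; the submitters' processing notes name RMA and Partek 6.6. Which arrays were normalized together, and which annotation was used, is not given in the sources used here. The authors' deposited table of an analysis of variance gives, for each probe set, a ratio of Bmp4 over control, a signed fold change, an F score, a p-value and an adjusted p-value, per the file headers. Its F and p fit 3 residual degrees of freedom, which is 5 arrays in 2 groups. Over 45101 probe sets, its log2 ratios correlated at r = 0.965 with those of the deposited values without control tumour 1, and at r = 0.749 with those of all 6 arrays. Across probe sets, which are not independent replicates, no other single omission exceeded r = 0.771. The deposited values hold all 6 arrays.

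Of the 45101 probe sets, 64 were control probe sets, 5905 had no gene symbol in the authors' deposited table, 2273 had several and 36859 had 1. Probe sets with no symbol or several were left out. Symbols were updated through a RefSeq gene table of the mouse assembly GRCm38.p6, which was used for names alone. Of the resulting 20401 genes, 14117 had a current symbol, 2815 were renamed through a transcript accession and 766 through a synonym that pointed to a unique gene, and 2703 kept the name in the file. Each gene was represented by the probe set with the highest mean over all 6 arrays, chosen without regard to the groups. No filter on dim probe sets was applied.

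Genes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 2 groups, two-sided), with Benjamini-Hochberg adjustment over the 20401 genes and a threshold of adjusted p under 0.05. Differences are Bmp4 minus control on the log2 scale. With 3 tumours against 3, an exact two-sided permutation test of a single value cannot go below p = 0.1, so tests of single genes rest on limma's spread pooled over genes. The number of arrays limits the precision.

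Before the data were examined, 30 gene lists were fixed from textbook knowledge of BMP signalling, tumour stroma and immune cells, and 592 of their 638 distinct symbols were measured. Lists with at least 5 measured members were tested with limma's camera, two-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists. Camera compares a list with all other genes. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance in 1 direction without reference to other genes, were alternatives. Members were also adjusted over the list alone.

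The rule for the genes named was fixed at the same time. It took Bmp4, 20 genes of BMP signalling, cytokines and myeloid cells whatever their values, the 12 genes with the largest difference in each direction among those past the threshold, and up to 4 members of each list with the smallest p. Where no gene passed, it took the 12 smallest p in that direction, to be called not significant. Predicted genes were left out of the 12. Probe sets of a named gene that opposed the chosen probe set with both p under 0.05 were to be named. Genes named outside this rule are said to be so, and not every gene that it took is reported here.

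Alternatives fixed in advance were quantile normalization again, centring of each array on its median or 75th percentile, filters at the 25th and 50th percentile of mean signal, the mean of a gene's probe sets, every probe set tested alone, eBayes with trend and robust options, no variance moderation, array weights, tumour number as a replicate block, at least a 2-fold difference, adjusted p under 0.01, the p of the authors' deposited table, each tumour left out in turn, and the other list tests. Omission of both control tumours 1 and 2, and omission of control tumour 1 combined with quantile normalization, trend and robust options, an estimated correlation or fry, were chosen after the data were seen.

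The scripts were tested on simulated data with 200 of 20401 genes changed, in 5 draws. With the spread of all 6 arrays, 0% of 2-fold, 21.2% of 4-fold and 47.6% of 8-fold changes were recovered. With the spread of the 5 arrays without control tumour 1, recovery was 35.2%, 77.0% and 92.4%. A T cell list shifted by 1 log2 unit was called in 5 of 5 draws in either setting, and 0 other lists were called. The simulated genes varied independently of each other, whereas the correlation estimated within the T cell list was 0.27 with all 6 arrays. The simulation therefore does not show how often camera calls a list falsely in these data. It also gave every array of a gene the same spread, whereas control tumour 1 stood apart in the data. The recovery rates therefore hold for arrays of equal spread.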

Results

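The data were log2 RMA expression values of 6 whole primary mammary tumours grown from 4T1.2 cells, a metastatic line derived from the mouse mammary carcinoma 4T1, in the mammary fat pad. The comparison was between 3 tumours of cells with an empty retroviral vector (control tumours) and 3 tumours of cells with the same vector carrying Bmp4 (Bmp4 tumours). BMP4 is a secreted ligand of the TGF-beta superfamily that signals through SMAD1, SMAD5 and SMAD9. The question was which genes differ in whole tumours, cancer cells and host cells together, when BMP4 expression is enforced. Array medians lay between 5.73 and 6.17.

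The array of control tumour 1 stood apart. Across probe sets, which are not independent replicates, it correlated with the other arrays at r = 0.655 to 0.719, while the other 5 correlated with each other at 0.959 to 0.993. Its interquartile range was 2.25, against 3.36 to 3.77 on the other arrays. Its hybridization controls, which are spiked into the labelled sample, averaged 12.84 against 9.79 to 10.97. By group, the hybridization controls averaged 10.42 to 12.84 in control tumours and 9.79 to 10.09 in Bmp4 tumours. The interquartile ranges were 2.25 to 3.64 and 3.67 to 3.77, so the groups overlapped in neither measure, with or without control tumour 1. Differences between the groups given below cannot be told apart from these measures. Control tumour 2 was the only array with signal from poly-A control transcripts, which are added to RNA before labelling. Their 3' probe sets averaged 11.54 there and 4.39 to 4.96 on the other arrays. The difference between 3' and 5' probe sets of Actb, which grows as RNA is degraded, was 2.62 to 5.64 in the control tumours and 1.44 to 2.33 in the Bmp4 tumours, so the groups did not overlap. For Gapdh it was 2.46 to 5.31 and 1.62 to 3.13, and the groups overlapped through control tumour 1 (2.46) alone. Control tumours 2 and 3, at 5.31 and 3.93, lay above every Bmp4 tumour, so without control tumour 1 Gapdh separated the groups too. Comparisons are given below with all 6 arrays and, because the authors' deposited table fits 5 arrays, without control tumour 1.

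**Figure D1:**
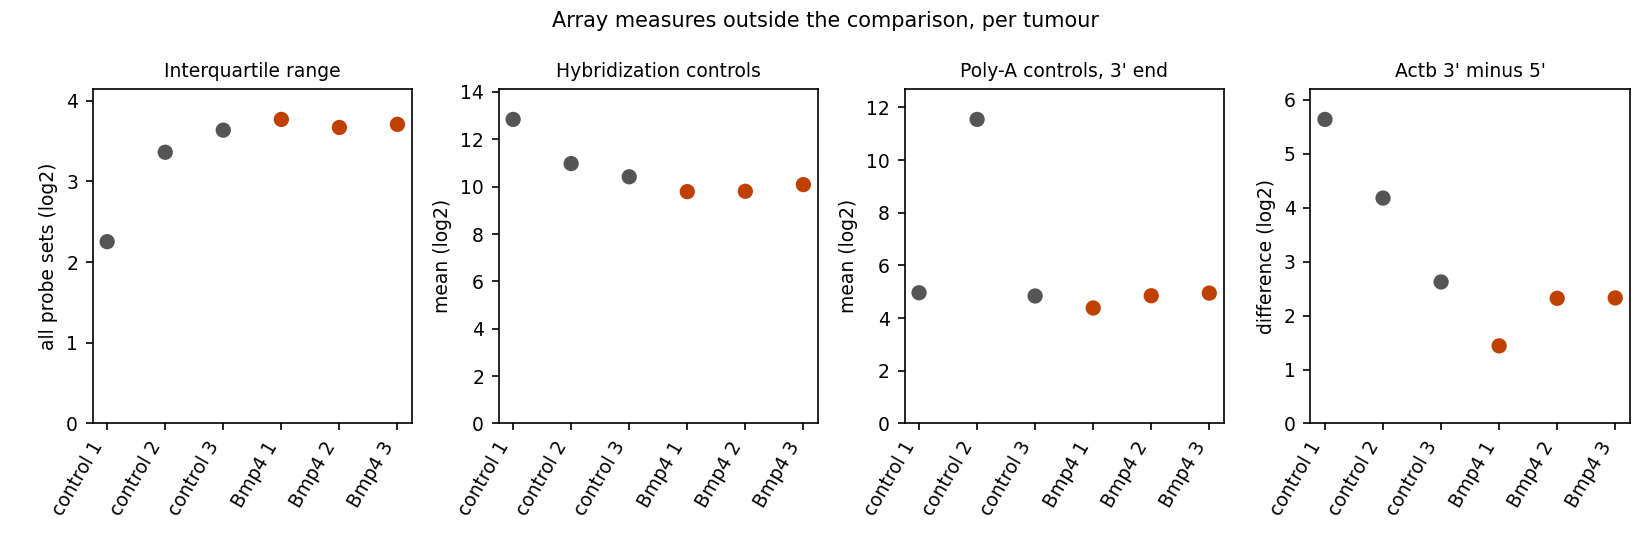
Array measures per tumour on the log2 scale, with control tumours in grey and Bmp4 tumours in orange: interquartile range of all probe sets, mean of the hybridization controls, mean of the 3' poly-A control probe sets, and the 3' minus 5' difference of Actb. Control tumour 1 has the smallest interquartile range (2.25) and the highest hybridization controls (12.84), and control tumour 2 alone has poly-A signal (11.54).

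Bmp4 transcript, measured by the probe set 1422912_at alone, was not higher in the Bmp4 tumours. Its level was 5.80 ± 0.75 (SD, n = 3) in control tumours and 5.16 ± 0.30 (SD, n = 3) in Bmp4 tumours, a difference of -0.64 ± 0.43 (SE; limma adjusted p = 0.496), and without control tumour 1 the difference was -0.30 ± 0.31 (SE; adjusted p = 0.646). The values were 6.48, 5.93 and 4.99 in control tumours 1 to 3 and 5.04, 4.94 and 5.51 in Bmp4 tumours 1 to 3. The values of control tumour 3 and of all 3 Bmp4 tumours lay below the median of all probe sets, 5.92. Whether the probe set lies within the vector's insert is not given in the sources used here, so it checks no label, and the groups are named below as the labels name them. The authors' deposited table gives a ratio of 0.856 for this probe set.

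Smad6, Smad7, Id1, Id2 and Id3, which BMP signalling is known to induce, had higher means in the Bmp4 tumours with all 6 arrays, although none passed the threshold over all genes. The list of 24 measured BMP-SMAD response genes that holds them was not shifted, with 12 members positive and 12 negative, a median of 0.00 and a mean of 0.44 (camera adjusted p = 0.291). Its median without control tumour 1 was -0.08 and its mean 0.24 (camera adjusted p = 0.108). Without control tumours 1 and 2, where control tumour 3 alone remains, its median was 0.13 and its mean 0.26. Smad6, an inhibitory SMAD, averaged 5.59 ± 0.45 (SD, n = 3) in control tumours and 8.04 ± 0.49 (SD, n = 3) in Bmp4 tumours, a difference of 2.45 ± 0.38 (SE; limma adjusted p = 0.496), with every Bmp4 tumour above every control tumour. Leaving out control tumour 1 gave 2.19 ± 0.28 (SE; adjusted p = 0.135). Id1, an inhibitor of basic helix-loop-helix factors, differed by 1.44 ± 0.33 (SE), and by 1.53 without control tumour 1. For Id2 the difference was 1.92 and then 0.87, for Smad7 1.56 and 0.90, and for Id3 1.37 and 0.26. The Id3 values of the groups overlapped, and without control tumours 1 and 2 its difference was -0.02. Adjusted over the list alone, 1 member was higher with all 6 arrays and 7 were higher without control tumour 1; over all genes tested, 0 were. The BMP antagonist Grem1 differed by -0.62, and by -0.46 without control tumour 1, not past the threshold. Nog, another, lay below the 25th percentile of all probe sets on all 6 arrays, so no difference is given. The Actb 3' minus 5' difference separated the same 2 groups.

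The list of BMP receptors and SMADs rose by camera (median 0.88, adjusted p = 0.00462; adjusted p = 0.711 with an estimated correlation). Its median was 0.12 without control tumour 1 (adjusted p = 0.0245; adjusted p = 0.562 with an estimated correlation). Of 19 measured members, 0 passed adjusted over the list alone with all 6 arrays and 5 were higher without control tumour 1. Bmpr1a, a type I BMP receptor, differed by 1.52 and 0.82 in the 2 settings, and Tgfbr2, the type II TGF-beta receptor, by 2.29 and 0.84. The TGF-beta response list rose as well (median 1.1, adjusted p = 0.0412; adjusted p = 0.711 with an estimated correlation), with a median of 0.15 without control tumour 1 (adjusted p = 0.0216; adjusted p = 0.680 with an estimated correlation). Its members went both ways. Ccn2, a matricellular protein, differed by 2.66 ± 0.64 (SE) and Col1a1, a fibrillar collagen chain, by -1.1 ± 0.36 (SE), and without control tumour 1 by 1.95 and -1.32. The other Col1a1 probe set, 1423669_at, differed by 0.63, and by -0.15 without control tumour 1. Adjusted over the list alone, 0 of 17 members passed with all 6 arrays, and 4 were higher and 1 lower without control tumour 1. The lists of BMP and TGF-beta ligands and of BMP antagonists were not shifted (adjusted p = 0.493 and 0.595). For these lists as well, the groups were separated by the Actb 3' minus 5' difference.

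No gene passed the threshold with all 6 arrays. Of 20401 genes, limma called 0 higher and 0 lower in Bmp4 tumours, and the smallest adjusted p was 0.358. At an unadjusted p under 0.05 there were 762 higher and 237 lower, 999 in all, against 1020 expected by chance. The groups did not overlap in 5415 genes (26.5%), where chance gives 10% on average. Genes on the same arrays are not independent, and array measures separated the same groups, so the excess is not a test of the groups. The median difference of all genes was -0.12, and that of genes above the median of mean signal was 0.44. Camera compares a list with all other genes, bright and dim, so its calls with all 6 arrays can depend on how bright the members are. Without control tumour 1, 4 genes were higher and 0 lower, with 1851 higher and 1156 lower at an unadjusted p under 0.05, and the median of all genes was -0.04. With control tumours 1 and 2 both left out, 0 genes passed in either direction, with 1130 higher and 927 lower at an unadjusted p under 0.05.

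The 4 genes that rose without control tumour 1 were Tnfrsf11b, Kazald1, Scara5 and Lad1, all among the 12 smallest p with all 6 arrays. Tnfrsf11b encodes osteoprotegerin, a decoy receptor for the osteoclast factor RANKL. Its level was 4.06 ± 0.74 (SD, n = 3) in control tumours and 8.74 ± 0.38 (SD, n = 3) in Bmp4 tumours, a difference of 4.68 ± 0.44 (SE; limma adjusted p = 0.358), and without control tumour 1 it was 4.26 ± 0.25 (SE; adjusted p = 0.0293). Its control values of 3.23, 4.66 and 4.28 lay near or below the 25th percentile of all probe sets on those arrays (5.04, 4.44 and 4.30). No call against background was used here, so the size of these differences, 25.6-fold and 19.2-fold, is uncertain. The authors' deposited table gives a smaller ratio of 13.45 for this probe set, with an adjusted p of 0.523 from its analysis of variance. The other Tnfrsf11b probe set, 1418309_at, which is dim (mean 4.98), differed by 0.26, and by 0.64 without control tumour 1. Kazald1, a secreted protein of the IGF-binding family, differed by 2.62 with all 6 arrays and 2.5 without control tumour 1 (adjusted p = 0.0443). Scara5, a ferritin receptor, differed by 2.27 and 2.05 (limma adjusted p = 0.0443), and its dim probe set 1431336_at (mean 5.51) by -0.30 and 0.08. Lad1, an anchoring filament protein of basement membranes, differed by 2.93 and 2.48 (adjusted p = 0.0465). The other 8 of the 12 smallest p among higher genes were not significant in either setting. They were Itih2 (2.92), Rnf128 (2.47), Smad6, Perp (2.0), the T cell receptor segment Tcrb-J (1.92), Ccr7 (2.06), Phlda2 (1.46) and Ano1 (1.84). In all 12, every Bmp4 tumour lay above every control tumour, and the Actb 3' minus 5' difference separated the groups as well.

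The 12 smallest p among lower genes were likewise not significant (limma adjusted p = 0.496 for each). Rapgef3, an exchange factor activated by cyclic AMP, differed by -1.89 ± 0.42 (SE), and Rbms3, an RNA-binding protein, by -1.74. Mpp3 differed by -1.55, St3gal1 by -1.52, Aplnr, the apelin receptor, by -1.48, and Pcdh12, a cadherin of endothelial cells, by -1.42. Ceacam10 differed by -1.48. The size of this difference is uncertain, since its Bmp4 tumour values of 3.81, 4.04 and 4.36 lay near or below the 25th percentile of all probe sets (4.24, 4.28 and 4.26). Lpar1, a lysophosphatidic acid receptor, differed by -1.34, Tomm22 by -1.32, Camkk2 by -1.30, H60, a ligand of the NK cell receptor NKG2D, by -1.14, and Tkfc by -1.02. Other probe sets differed less with all arrays: Tomm22 1429103_at by -0.02, Camkk2 1455401_at by 0.19 and 1424475_at by -0.36. Lpar1 1417143_at differed by -0.17 and St3gal1 1418946_at by 0.21. Without control tumour 1 these differed by -0.36, -0.46, -0.85, -0.71 and -0.16. For these genes the size of the fall depended on the probe set. The other probe sets of Rapgef3, Rbms3, Aplnr, Pcdh12, Ceacam10 and Mpp3 were negative in both settings. Every Bmp4 tumour lay below every control tumour in the 12 chosen probe sets, as in the Actb 3' minus 5' difference. Without control tumour 1 the adjusted p of Rapgef3 was 0.055 and that of Pcdh12 0.057.

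**Figure D2:**
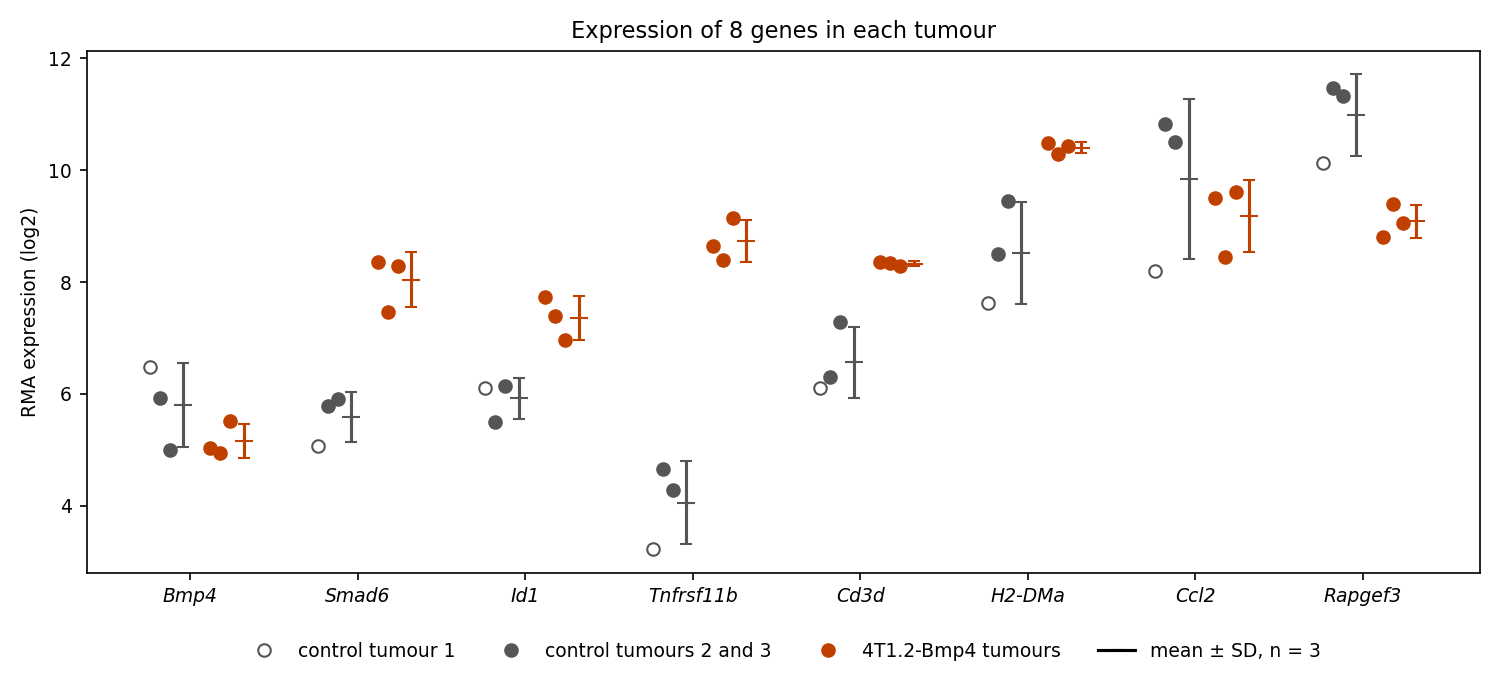
Log2 RMA expression of 8 genes in each tumour, with control tumours in grey (control tumour 1 open), Bmp4 tumours in orange and bars for the mean ± SD (n = 3). Tnfrsf11b averages 4.06 in control and 8.74 in Bmp4 tumours and Smad6 5.59 and 8.04, while Bmp4 averages 5.80 and 5.16.

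Markers of T cells rose as a list in the Bmp4 tumours. The median difference of 18 measured members was 1.12 with all 6 arrays (camera adjusted p = 3.08e-07) and 1.13 without control tumour 1 (adjusted p = 1.22e-07). With an estimated correlation the adjusted p was 0.711 and 0.562. Adjusted over the list alone, 11 members were higher with all 6 arrays and 12 without control tumour 1, and over all genes tested 0 passed. Cd5 differed by 1.97 ± 0.41 (SE), Cd2 by 1.82 ± 0.39 (SE) and Cd3d, a chain of the receptor complex, by 1.77 ± 0.37 (SE). Leaving out control tumours 1 and 2 gave differences of 1.2, 1.14 and 1.05 for these genes, and a median of 0.97 and a mean of 0.66 for the list. The mean of the list was 6.94, 6.70 and 7.54 in control tumours 1 to 3 and 8.32, 8.11 and 8.16 in Bmp4 tumours 1 to 3.

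NK and cytotoxic cell markers rose too, by a median of 0.68 over 19 members (camera adjusted p = 0.000233) and 0.64 without control tumour 1 (adjusted p = 0.000326). With an estimated correlation the adjusted p was 0.711 and 0.562. Adjusted over the list alone, 5 members were higher with all 6 arrays and 0 without control tumour 1. Fasl, the ligand of the death receptor FAS, differed by 2.55 ± 0.63 (SE), the granzyme Gzmd by 2.5, and Klrd1 and Nkg7 by 2.24 and 1.78. The size of the Gzmd difference is uncertain. Its control values of 3.39, 5.05 and 4.08 lay below the 25th percentile of all probe sets on 2 of the 3 arrays. With control tumours 1 and 2 left out, Fasl, Klrd1 and Nkg7 differed by 1.43, 0.89 and 0.95. B and plasma cell markers rose by a median of 1.09 (adjusted p = 0.00719), and 0.90 without control tumour 1 (adjusted p = 0.0140), and 0 of 15 passed adjusted over the list alone in either setting. The adjusted p with an estimated correlation was 0.711 and 0.680, and without control tumours 1 and 2 the median of the B cell list was 0.25. Ms4a1, which encodes CD20, differed by 1.48 and Cd79b by 1.17. The Actb 3' minus 5' difference also separated the groups in which these lymphocyte lists differed.

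Antigen presentation genes rose by a median of 1.73 (14 of 14 members positive; camera adjusted p = 2.04e-06), and by 0.63 without control tumour 1 (adjusted p = 2.87e-07). With an estimated correlation the adjusted p was 0.711 and 0.562. Adjusted over the list alone, 0 passed with all 6 arrays and 9 were higher without control tumour 1. The class II genes H2-DMa, H2-Eb1 and H2-DMb1 differed by 1.88 ± 0.48, 1.86 ± 0.58 and 2.65 ± 0.87 (SE), by 1.43, 1.67 and 1.82 without control tumour 1, and by 0.96, 0.58 and 0.70 without control tumours 1 and 2. On the array of control tumour 1, H2-DMb1 (4.88) lay below the 25th percentile of all probe sets (5.04), as did Arg1 (4.86), Il6 (4.53) and Perp (4.93). Type I and II interferon response genes rose by a median of 0.72 (26 of 30 positive; adjusted p = 0.000201; adjusted p = 0.711 with an estimated correlation), and 0.29 without control tumour 1 (adjusted p = 0.00527; adjusted p = 0.562 with an estimated correlation), with 0 past the adjustment over the list alone. The chemokine Cxcl9 differed by 1.53 and the immunoproteasome subunits Psmb9 and Psmb8 by 1.29 and 1.62; without control tumour 1 these were 1.03, 0.72 and 0.87. In this class, too, control tumour 1 lay lowest, as the antigen presentation means of 8.66, 10.30 and 10.97 in control tumours 1 to 3 and 11.52, 11.40 and 11.51 in Bmp4 tumours 1 to 3 show, and the Actb 3' minus 5' difference separated the groups.

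Monocyte and macrophage markers rose by a median of 1.2 (camera adjusted p = 2.29e-06; adjusted p = 0.711 with an estimated correlation) and 0.91 without control tumour 1 (adjusted p = 1.50e-05; adjusted p = 0.680 with an estimated correlation). Adjusted over the list alone, 0 of 28 passed in either setting. Lyz2, a lysozyme of myeloid cells, differed by 2.35 ± 0.60 (SE), Arg1, arginase 1, by 3.18 ± 1.21 (SE) and the Fc receptor Fcgr3 by 1.80. They differed without control tumour 1 by 1.87, 1.87 and 1.25, and without control tumours 1 and 2 by 1.22, 0.70 and 0.57, where the median of the list was 0.07. Neutrophil and granulocytic suppressor cell markers were not shifted (median 0.08, camera adjusted p = 0.635, and 0.852 without control tumour 1). Without control tumours 1 and 2 their median was -0.35, with 18 of 25 negative. Their members S100a8 and S100a9 differed by -0.59 and -0.50, by 0.12 and 0.17 without control tumour 1, and by -0.48 and -0.48 without control tumours 1 and 2, so the direction depended on both of these arrays. Ngp, a granule protein, differed by -1.39 ± 0.56 (SE). Mmp9 differed by 0.80, and by 0.03 without control tumour 1. Dendritic cell markers were not shifted (camera adjusted p = 0.282). In mast cell, basophil and eosinophil markers camera gave adjusted p = 0.123, and 0.0220 without control tumour 1 (adjusted p = 0.680 with an estimated correlation). Their medians were 0.44 and 0.28 in these settings, and 0.14 without control tumours 1 and 2. Between the groups of these myeloid lists, too, the Actb 3' minus 5' difference did not overlap.

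Cytokines that recruit myeloid cells did not pass the threshold as single genes. Csf3, which encodes G-CSF, differed by -0.41 ± 1.1 (SE; limma adjusted p = 0.799), and by -1.32 ± 0.89 (SE; adjusted p = 0.493) without control tumour 1; its levels were 7.54, 11.69 and 8.88 in control tumours 1 to 3, and without control tumours 1 and 2 it differed by 0.09. Ccl2 differed by -0.66 ± 0.75 (SE), and without control tumour 1 by -1.48 ± 0.36 (SE; adjusted p = 0.243). Il6 differed by 1.31, by -0.26 without control tumour 1 and by 0.85 without control tumours 1 and 2. Csf2 differed by -0.07, Cxcl1 by -0.22, Ccl5 by 0.79, Il1b by 1.88, Nos2 by -0.93 and Cd274, which encodes the checkpoint ligand PD-L1, by 1.38 ± 0.59 (SE). These became, without control tumour 1, -0.12, -0.42, 0.43, 0.72, -0.40 and 0.72, in the same order, and without control tumours 1 and 2 Csf2 and Nos2 differed by 0.36 and 0.07. The list of myeloid growth factors and recruiting chemokines rose with all 6 arrays (median 0.40, adjusted p = 0.0414; adjusted p = 0.711 with an estimated correlation) and was not shifted without control tumour 1 (median -0.04, adjusted p = 0.892). Its member with the smallest p, Cxcl15, differed by 1.74 ± 0.35 (SE) and, without control tumour 1, by 1.99. NF-kappaB targets were not shifted (median 0.75, adjusted p = 0.0583, and -0.10, adjusted p = 0.766, without control tumour 1). By camera they were called higher without control tumour 2 (median 1.1, adjusted p = 0.000216) and without Bmp4 tumour 2 (0.83, adjusted p = 0.0259). With array weights they were called lower (-0.30, adjusted p = 0.0217), a fit in which control tumour 2 carried nearly all of the control weight. Their median without control tumours 1 and 2 was 0.32. With an estimated correlation the adjusted p was 0.750 with all 6 arrays. The separation of the groups in the Actb 3' minus 5' difference applied here too.

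Several list calls rested on control tumour 1. With all 6 arrays, hypoxia and glycolysis genes (median 0.77, camera adjusted p = 0.00719), extracellular matrix proteases and inhibitors (0.72, adjusted p = 0.0241) and cell cycle genes (0.54, adjusted p = 0.0295) rose, and erythroid and platelet markers (-0.49, adjusted p = 0.0280) and skeletal muscle markers (-0.50, adjusted p = 0.0414) fell. With an estimated correlation the adjusted p of each was 0.711. Their medians without control tumour 1 were 0.10, -0.02, 0.05, -0.20 and -0.03, with adjusted p = 0.686, 0.892, 0.852, 0.0902 and 0.852. In the other direction, endothelial markers were not shifted with all 6 arrays (median -0.11, adjusted p = 0.413) and fell without control tumour 1 (median -0.52, adjusted p = 0.000286; adjusted p = 0.562 with an estimated correlation), where 4 of 21 were lower adjusted over the list alone. The groups did not overlap in the Actb 3' minus 5' difference for these lists either.

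Of the 30 lists, camera called 14 with all 6 arrays, 12 higher and 2 lower, and 10 without control tumour 1, 9 higher and 1 lower. With an estimated correlation 0 were called in either setting. The lists called in the same direction in both numbered 8. Of cell markers these were the T cell, NK and cytotoxic, B and plasma, and monocyte and macrophage lists. The rest were antigen presentation, interferon response, TGF-beta response, and BMP receptors and SMADs. Both settings share every array but control tumour 1, so the second does not replicate the first. Without control tumours 1 and 2, control tumour 3 alone remains and no call is given. The medians of these lists there were, in the same order, 0.97, 0.59, 0.25, 0.07, 0.51, 0.28, 0.45 and 0.04. Lists not shifted in the first 2 of these settings also included fibroblast and pericyte markers (adjusted p = 0.289 with all 6 arrays), adipocyte markers (0.282), luminal epithelial markers (0.432), basal and keratinocyte markers (0.437), mesenchymal transition genes (0.479), cartilage and bone genes (0.626), Wnt and Notch genes (0.635) and apoptosis and p53 genes (0.0914). The median and the mean of the Wnt and Notch list differed in sign (-0.08 and 0.10), as did those of the ligand list (-0.39 and 0.04) and of the cartilage and bone list (-0.23 and 0.21). In the luminal list Esr1 differed by 1.19; its probe set 1421244_at, which is dim, opposed the chosen probe set without control tumour 1 (-0.39 against 0.77).

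**Figure D3:**
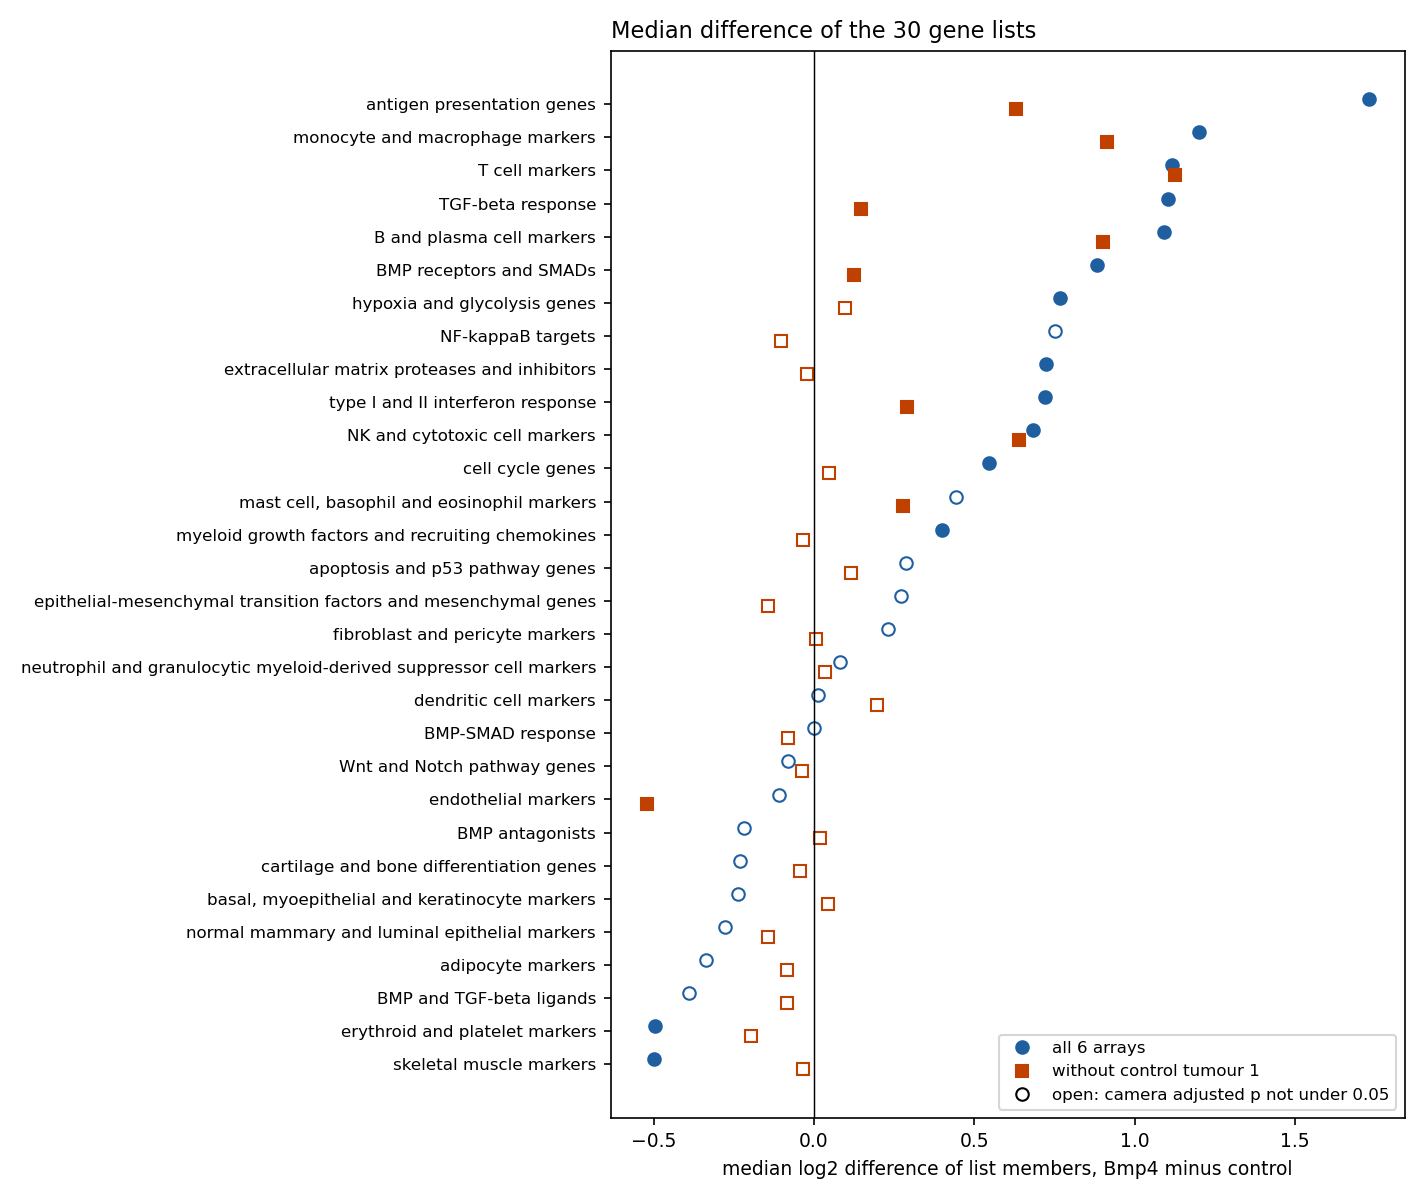
Median log2 difference (Bmp4 minus control) of the members of the 30 gene lists, with all 6 arrays (blue circles) and without control tumour 1 (orange squares), filled where camera's adjusted p is under 0.05. The T cell median is 1.12 and 1.13 in the 2 settings, while that of hypoxia and glycolysis genes is 0.77 and 0.10.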

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

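The tests of the array of control tumour 1 were chosen after its values were seen. 2 signals lay outside the comparison, both in control probe sets. Poly-A control transcripts averaged 11.54 on the array of control tumour 2, against at most 4.96 on the others. Hybridization controls averaged 12.84 on the array of control tumour 1, against at most 10.97 on the others. Those of control tumours 2 and 3, 10.97 and 10.42, also lay above the highest Bmp4 tumour, 10.09, so this measure separated the groups.

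The array of control tumour 1 may have received little labelled target from the tumour: its hybridization controls lay 1.87 above the highest of the other 5 arrays, as a fixed amount of spike would with less competing signal. Its interquartile range of 2.25, which lay -8.75 SDs of the other 5 arrays from their mean, is part of the pattern and says nothing on which sample it holds, so a swapped sample stays open. Degraded RNA stays open as well. The 3' minus 5' difference was highest on this array for 1 of 2 control genes, Actb (5.64), while for Gapdh (2.46) it lay within the range of the others. No biological explanation was tested for this array. Whether the array of control tumour 2 was labelled in a batch of its own is not given in the sources used here, and why it alone shows the poly-A signal was not tested.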

How the results depend on the processing

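Omission of control tumour 1 combined with another choice, and omission of control tumours 1 and 2, were chosen after the data were seen; the other settings were fixed before. With all 6 arrays, limma called 0 genes in either direction under every planned setting except array weights, which called 5147 higher and 6160 lower. The weights ran from 0.027 for control tumour 1 to 44.8 for control tumour 2. Control tumour 3 had a weight of 0.154, so control tumour 2 carried nearly all of the control weight in that fit. The p of the authors' deposited table, an analysis of variance that fits 5 arrays, called 1 higher (Tnfrsf19, named after its value was seen) when adjusted over the 20401 genes. Leaving out each tumour in turn gave 0 to 4 higher and 0 lower; the 4 came without control tumour 1. Without it, quantile normalization again called 5 higher and 1 lower (Pcdh12), and the trend and robust options 5 higher and 2 lower (Rapgef3 and Col24a1, the second named after its value was seen). Both added Itih2 to the 4. The cause was not tested.

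The Bmp4 difference was -0.72 with array weights (limma adjusted p = 0.00220), where control tumour 2 carried nearly all of the control weight. It was -1.04 to -0.30 with a tumour left out, and 0.17 without control tumours 1 and 2. Over its alternatives other than this last omission, the limma adjusted p ran from 0.00220 to 0.765. The filter at the median of mean signal removed Bmp4.

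The count of 14 lists became 8 after quantile normalization again, 4 with genes above the median of mean signal, and 0 with an estimated correlation and 0 with fry. Without control tumour 1 it was 8 after quantile normalization again, 0 with an estimated correlation and 0 with fry. It was 10 to 16 with a tumour left out. T cell, NK and antigen presentation lists kept their call and direction in 20 of 24 alternatives and lost it in the 4 with fry or an estimated correlation.

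Directions turned with array weights for Il6 (-1.28), S100a8 (0.72), S100a9 (0.78), NF-kappaB targets (-0.30), myeloid growth factors (-0.31) and matrix proteases (-0.14). Leaving out control tumour 1 alone turned the medians of BMP-SMAD response genes (-0.08), BMP antagonists (0.02), NF-kappaB targets (-0.10), myeloid growth factors (-0.04), basal markers (0.04), mesenchymal genes (-0.14) and matrix proteases (-0.02), none of them called there. Without control tumour 1 and with quantile normalization they turned for myeloid growth factors (-0.10), skeletal muscle (0.030), cell cycle (-0.044), hypoxia (-0.0012) and matrix proteases (-0.025; -0.021 with fry). Without control tumours 1 and 2 the medians turned for neutrophil (-0.35), cell cycle (-0.18), BMP antagonist (0.06), adipocyte (0.11) and luminal (0.02) lists. Those of basal (0.07), cartilage and bone (0.16) and Wnt and Notch (0.05) lists turned too. The skeletal muscle median stayed negative there (-0.011), while its mean was 0.043. The cause was not tested. Of 153 genes that the rule took other than Bmp4, 136 kept their sign in all settings, and 17 did not: Csf2, Il6, S100a9, Csf3, S100a8, Mmp9, Nog, Adrb3, Car3, Cxcl1, Eng, Id3, Itgax, Krt7, Mmp11, Nos2 and Pmaip1. NF-kappaB targets were called higher in 7 of 24 alternatives and lower in 1, array weights (adjusted p = 0.0217; range over the alternatives 0.000216 to 0.979).

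Centring on the 75th percentile moved the median of all genes from -0.12 to -0.42, and centring on the median to 0.06. Deviations of tumours of the same number correlated at r = -0.14, -0.25 and -0.04, against -0.12 to 0.23 for different numbers. With 3 tumours per group and control tumour 1 standing apart, these values cannot tell whether the numbers pair the tumours. The replicate block gave 0 genes higher, 0 lower, 15 lists and a Bmp4 difference of -0.64. Simulated 2-fold changes, drawn with equal spread on every array, were recovered in 0% with 6 arrays and 35.2% without control tumour 1.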

Other observations

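All tests in this part except the lymph node list and the counts over splits were chosen after the results were seen. Without control tumour 1, symbols of unnamed clones made up 3.24% of 1851 genes higher and 20.4% of 1156 genes lower at an unadjusted p under 0.05, against 18.8% of all genes. In the hypoxia list, P4ha1, a collagen prolyl hydroxylase, differed by 2.13, and by 1.0 without control tumour 1, while Adm, adrenomedullin, differed by -0.84 and -1.0. The macrophage elastase Mmp12 differed by 2.46 and 1.68, and mast cell proteases Cpa3 and Tpsab1 by 2.0 and 2.24, by 1.89 and 2.05 without control tumour 1, and by 0.80 and 0.69 without control tumours 1 and 2; none of these passed the threshold over all genes.

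T cell markers were higher in the tumours labelled Bmp4, and the array of control tumour 1 alone is argued against, since without it the mean of the list still differed by 1.08 ± 0.32 (SE), and by 0.66 without control tumour 2 as well. A piece of lymph node in the excised tissue stays open. A list of 15 lymph node genes, 11 measured and 6 of them also in the B cell list, was written before its test. It cannot decide, because a lymph node itself holds T cells and could raise their markers by more than its other genes. The T cell list exceeded the lymph node list by 1.05 ± 0.39 (SE) with all 6 arrays and 0.77 ± 0.36 (SE) without control tumour 1. Both values met the bound of 2 SE set beforehand. The margin was narrow: with the 5 members below the median of all probe sets left out, a check added after the first value was seen, the excess was 0.83 ± 0.36 and 0.56 ± 0.31 (SE), the latter under 2 SE, and the follicle B cell genes Ms4a1 and Cd79b differed by 1.84 and 1.07 without control tumour 1. RNA integrity stays open, since the lowest control tumour exceeded the highest Bmp4 tumour by 0.30 in the Actb 3' minus 5' difference. The hybridization controls and the interquartile range separated the groups as well, so an effect of the arrays stays open too. More T cells in Bmp4 tumours remains an untested hypothesis.

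The means of Smad6, Smad7, Id1, Id2 and Id3 were higher in the tumours labelled Bmp4 with all 6 arrays, none past the threshold over all genes, while that of Bmp4 was not, and without control tumours 1 and 2 Id3 differed by -0.02. More BMP signalling stays an open hypothesis. The median difference of the 5 genes was 1.56 with all 6 arrays and 0.90 without control tumour 1. Each gene was fixed beforehand, but this set of them was tested after their means were seen. These medians lay at percentiles 98.8 and 99.9 of 10000 random sets matched on mean expression. Genes drawn at random need not vary together, as genes induced by the same signal may, so the percentiles cannot decide. The fixed list of 24 BMP-SMAD response genes was not shifted (camera adjusted p = 0.291 and 0.108). It had 12 positive and 12 negative members with all 6 arrays, and its median without control tumours 1 and 2 was 0.13. A swap of the 2 groups stays open too, since the Bmp4 probe set checks no label and Smad6 belongs to the pattern itself. RNA integrity could not be told apart from the group, with the same Actb gap of 0.30. Neither could the hybridization controls and the interquartile range, which separated the groups as well.

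The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. All 10 gave as many genes as the real one, 0, with a highest other of 0. For lists, 4 of the 10 splits gave at least the real 14, the highest other being 16, and the lowest other 10. The 3 other splits with as many placed control tumour 1 with 2 Bmp4 tumours. Without control tumour 1, the real split of the 5 arrays gave 4 genes and 10 lists, and the other 9 splits gave 0 genes and 4 to 9 lists. These splits were added after the data were seen, and 10 splits are again too few for a share under 0.05.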
